A study of Caenorhabditis elegans with 2 samples.

How the data were processed

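The series holds 2 chromatin immunoprecipitation sequencing (ChIP-seq) libraries from Caenorhabditis elegans animals of the third larval stage (L3), taken as whole organisms of mixed sex. The strain, OP218, carries a transgene that expresses the product of gene R02D3.7 with an eGFP tag in an unc-119 mutant background, and the labels number the libraries as biological replicates 1 and 2 of 1 group. The annotation used here names R02D3.7 rcat-1, and both names refer to the same gene below. No control sample belongs to the samples analysed here, so no comparison between conditions was made. Sites of the tagged protein therefore cannot be told from sites that would be listed whatever protein is tagged, and "bound" below means only that a peak was listed.

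Per the labels and the deposited list of files, 4 peak lists in narrowPeak format were used on each of the ce11 and ce10 genome builds. They are a relaxed list for each replicate, a relaxed list for the pooled replicates, and an optimal list thresholded by the irreproducible discovery rate (IDR), a measure of how well ranks of regions repeat between replicates. The list of files states that each relaxed list was derived from an alignment of the replicate, or of both replicates, together with a control alignment. Both replicates share that control, so their lists are not fully independent. The signal value of each region is the authors' own, with a scale that is not given in the sources used here, and it served only to describe, rank or filter regions within a list. The −log10 q-value of each region was deposited by the authors beside the signal and was used only to describe the lists. The summit offset, deposited by the authors in bp from the region start, set the position of each summit. The caller, its version, the IDR threshold, the aligner and the read depth are not given in the sources used here, so no counting error could be attached to a single region and the depth per sample is unknown. Signal tracks and alignments were not used here.

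All coordinates are 1-based positions on ce11, which was compared by chromosome name and length with the reference genome used here, and no region reached beyond a chromosome end (0 regions). Genes were taken from Ensembl release 115. A promoter window ran from 1000 bp upstream to 200 bp downstream of an annotated transcript start of a protein-coding gene, and a gene counted as bound when an IDR summit lay in such a window. A summit in a divergent promoter therefore binds more than 1 gene, and which of them is regulated cannot be read from a peak list.

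Replicate agreement was measured across IDR peaks as Spearman and Pearson correlations of the highest overlapping region (at least 1 bp) in each relaxed list, with two-sided permutation tests of 100000 resamples, whose smallest possible p is 1.0e-05. Peak locations and noncoding gene classes were compared with 1000 random placements of the summits within their chromosomes. The smallest p that these allow is 9.990e-04 one-sided, used for the promoter share and list overlap, and 0.001998 two-sided, used for classes of location and of noncoding gene. Chromosome shares were compared with the share of nuclear genome length by exact binomial tests. Gene lists and sequence motifs were tested by two-sided Fisher's exact tests, with all protein-coding genes (19973) or the flanking windows as background. Odds ratios carry exact conditional 95% intervals, and a table with an empty cell had 0.5 added to each cell for the odds ratio alone. Motifs were searched on both strands in the 200 bp around each summit and in 2 flanking windows of the same length centred 500 bp to each side. P-values within each family were adjusted by the Benjamini-Hochberg method and called below 0.05. Peaks and genes are not independent replicates, so these p-values describe the lists of this experiment and not the spread between worm populations. Shares over rank classes carry Wilson 95% intervals, which cover counting error only.

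The groups, tests, windows, 27 gene lists, 23 motifs, most alternatives and the rule for named genes were fixed before the data were examined. The lists cover ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, splicing factors, histones, chaperones, the proteasome, the vacuolar ATPase, oxidative phosphorylation, cuticle collagens, molting and hedgehog-related genes, markers of intestine, muscle, pharynx, neurons, ciliated neurons and germline, major sperm proteins, epidermis and seam regulators, heterochronic genes, homeobox genes, nuclear hormone receptors, the Wnt pathway, the insulin and stress pathway, the cell cycle, tubulins and actins, and chemoreceptors. Members were taken by gene name pattern. The rule names the genes at the 20 IDR peaks of highest signal, up to 4 members with the highest promoter signal in each list past the threshold and 1 in each other list with a bound member, rcat-1 and unc-119, and the 5 six-mers of highest odds ratio. Any other gene or sequence named was chosen after its values were seen.

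The alternatives were the ce10 lists, the 50 percent of IDR peaks with the higher signal, the highest regions of 1 replicate alone in the same number as the IDR peaks, stricter overlaps (50 percent of the shorter region, or summits within 100 bp), promoter windows of 500 and 100 bp or 2000 and 500 bp, other backgrounds drawn from the pooled list, summits within 1000 bp counted once, coding transcript starts in place of genome length, a distance of 500 bp to noncoding genes, motif windows of 100 bp, and 50 kb in place of 20 kb around the tagged gene. Alternatives added after seeing the data were the 200 IDR peaks of highest signal, the peaks without the sequence element described in the closing section, leaving out chromosome I, and the tagged locus in each replicate alone. The ce10 lists were compared only by number, width, chromosome share and agreement, since coordinates were not moved between builds. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

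The procedures were tested on simulated data. For the gene lists, a planted list passed in 20 of 20 simulated peak sets, and 3 of 20 random sets had any list past the threshold. For motifs, a planted six-mer ranked first in 20 of 20 sets. Windows and flanks in these sets had the same base composition, so false calls from a difference in composition were not measured. For replicate agreement, 2 of 20 unrelated pairs gave a permutation p below 0.05. For the promoter share, 0 of 20 random sets did.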

Results

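The data map where the tagged product of R02D3.7 (rcat-1) was found on chromatin in L3 larvae of C. elegans, in 1 group of 2 biological replicates. On ce11 the relaxed lists held 30000 regions for replicate 1, 29367 for replicate 2 and 30000 for the pooled replicates, and the IDR list held 1584 peaks. The IDR peaks had a median width of 384 bp and covered 543 kb, or 0.542% of the 100 Mb nuclear genome. They were the 1584 regions of highest signal in the pooled list, with a signal from 50.7 to 4055, a median of 82.2 and 23 peaks above 1000. Their −log10 q-values ran from 2.95 to 3.43. The corresponding list on ce10 held 1574 peaks. Read depth per sample is unknown, so precision is described through the replicates.

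The peak of highest signal lay at the promoter of rcat-1 itself, and nearly all other leading peaks lay at promoters too, several of them of ribosomal protein genes. The rcat-1 peak (IV, 255406 to 255892, summit 255641, signal 4055) ranked 1 in replicate 1 and 2 in replicate 2, and its summit was 212 bp upstream of the transcript start. Rank 2 fell between Y17G9B.5 and rpl-20, which encodes a protein of the large ribosomal subunit (IV, 4749797 to 4750333, signal 3935). Rank 3 covered the promoters of rbc-2, Y54F10AM.15 and ndua-8, a gene of respiratory complex I (III, 2528558 to 2529058, signal 3017), and rank 4 that of sco-1, a cytochrome oxidase assembly gene (II, 4299123 to 4299770, signal 2905). Rank 5 lay at F25B4.4 and hmgs-1, the HMG-CoA synthase of the mevalonate pathway (V, 5684494 to 5684990, signal 2064).

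Ribosomal protein promoters were found at ranks 6 (ska-3 and rps-12; III, 5678882 to 5679359), 9 (rpl-15 and K11H12.8; IV, 654703 to 655154), 11 (rpl-23 and swp-1; III, 5706177 to 5706677), 15 (rbg-3 and rps-0; III, 4754133 to 4754598) and 19 (rpl-29 and thoc-7; IV, 13881728 to 13882151). With rpl-20 they made 6 of the first 20 peaks. Rank 7 lay at hat-1, a histone acetyltransferase gene, and M03C11.3 (III, 10407167 to 10407734), rank 8 at dld-1, which encodes dihydrolipoamide dehydrogenase (IV, 14464052 to 14464516), and rank 10 at exos-2, an RNA exosome gene (IV, 6415133 to 6415608). Ranks 12 and 13 lay at R05D3.8 and rfp-1 (III, 8358149 to 8358588) and at T23F6.3 and rbd-1 (IV, 12724627 to 12725079). Ranks 16 to 18 lay at F54D10.5 (II, 3808076 to 3808486), at frg-1 and ubq-2, a gene of a ubiquitin and ribosomal protein fusion (III, 12978779 to 12979248), and at gtsf-1 (IV, 16865485 to 16865921). Rank 20 lay at wapl-1, a cohesin regulator, and htz-1, the histone H2A.Z gene (IV, 4445693 to 4446086, signal 1083). Rank 14 was the exception, an intergenic peak (II, 10388006 to 10388464, signal 1284) whose nearest coding start, that of ztf-27, was 2903 bp away. Of the 20 peaks, 9 were on chromosome IV, 7 on III, 3 on II and 1 on V. All 20 ranked within the first 20 in replicate 1 and within the first 25 in replicate 2.

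The labels allow 1 comparison between samples, that of the replicates. The IDR peaks are the regions of highest signal in the list pooled from both replicates. Overlap with each replicate is therefore partly built in, and the values below are conditioned on that choice. Without it, 66.2% of the 1584 highest regions of replicate 1 overlapped one of the 1584 highest of replicate 2. Nearly all IDR peaks were found in both lists, 1573 of 1584 in the replicate 1 list and 1582 in the replicate 2 list, with 1571 in both. Signal across these 1571 peaks had a Spearman's rho of 0.633 and a Pearson's r of 0.976 (permutation p = 1.0e-05 each, two-sided, the smallest possible). Among the 1584 highest regions of each replicate, 84.2% of the IDR peaks were found in replicate 1 and 79.8% in replicate 2, against at most 2.15% and 2.08% in any of 1000 random placements (permutation p = 9.990e-04 each, the smallest possible). The median distance between the replicates' summits was 22 bp, and 76.6% lay within 50 bp of each other. Correlation was also computed within classes of signal. In the first 100 peaks, from rcat-1 down to a signal of 422, rho was 0.851 and the median summit distance 6.5 bp. It was 0.356 for ranks 101 to 200 and 0.145 for ranks 201 to 400 (adjusted permutation p = 0.0498). For ranks 401 to 800 it was -0.0983 (adjusted permutation p = 0.0498), and for ranks 801 to 1584 -0.453 (adjusted permutation p = 2.5e-05, 5 classes, two-sided). These classes were formed after the data were seen and were selected on pooled signal, which by itself pushes a correlation within a narrow class below 0. The first class spans signals from 422 to 4055 and the last from 50.7 to 81.5, so the classes do not show where in the list the replicates agree. Correlations across peaks are not correlations across independent replicates.

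**Figure D1:**
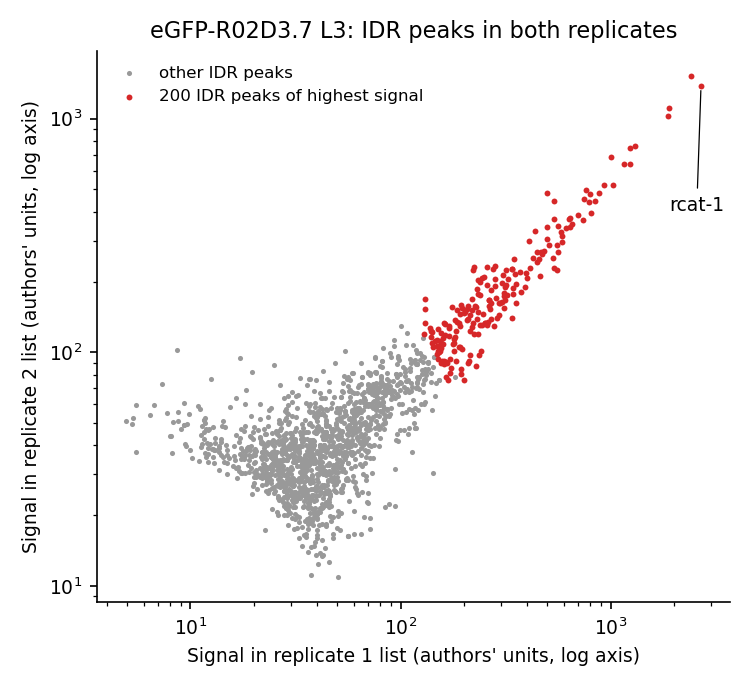
Signal of each IDR peak in the replicate 1 list (x axis, authors' units, log axis) against the replicate 2 list (y axis, authors' units, log axis), 1 point per peak, with the 200 peaks of highest signal in red. The 1571 peaks present in both lists have a Spearman's rho of 0.633.

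Where the peaks lie relative to genes was asked next. Promoters held 1104 of the 1584 summits (69.7%), 2.68-fold more than the 26.0% ± 1.09 (SD of 1000 placements) of random placement, none of which exceeded 29.8% (one-sided permutation p = 9.990e-04, the smallest possible). The depletion was largest in coding exons, with 10 summits (0.631% against 19.04% by chance), followed by introns, with 129 (8.14% against 27.6%), and 3' UTRs, with 12 (0.758% against 2.36%). Intergenic sequence held 261 (16.5% against 22.04%), also fewer than chance (adjusted permutation p = 0.00280 for each of these 4 classes, two-sided permutation test). The classes exclude each other, so the promoter excess by itself lowers the rest. Of the 480 summits outside promoters, more were intergenic (261) than in introns (129), whereas random placement put more in introns. Depletion among these summits alone was not tested. Noncoding exons held 59 (3.72% against 2.61%, adjusted permutation p = 0.00466), and the 9 in 5' UTRs did not differ from chance beyond the threshold (adjusted permutation p = 0.428).

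Summits gathered just upstream of starts. The median distance to the nearest coding transcript start was 296.5 bp, against 1280.5 bp for a random placement, and 80.7% lay upstream of it or at it. The 100 bp bin from 200 to 100 bp upstream held the most, 308 summits. In all, 1539 protein-coding genes (7.71%) were bound, and 451 peaks lay in the promoter windows of 2 or more genes, as at rpl-20, while 653 had 1 gene and 480 none. Summits of the pooled list outside the IDR peaks (28195) lay in promoters in 31.2% of cases, an odds ratio of 5.07 for the IDR peaks (Fisher's exact test, two-sided p = 3.522e-204). With promoter windows of 2000 and 500 bp the fold over chance was 1.72, and with 500 and 100 bp it was 4.28.

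**Figure D2:**
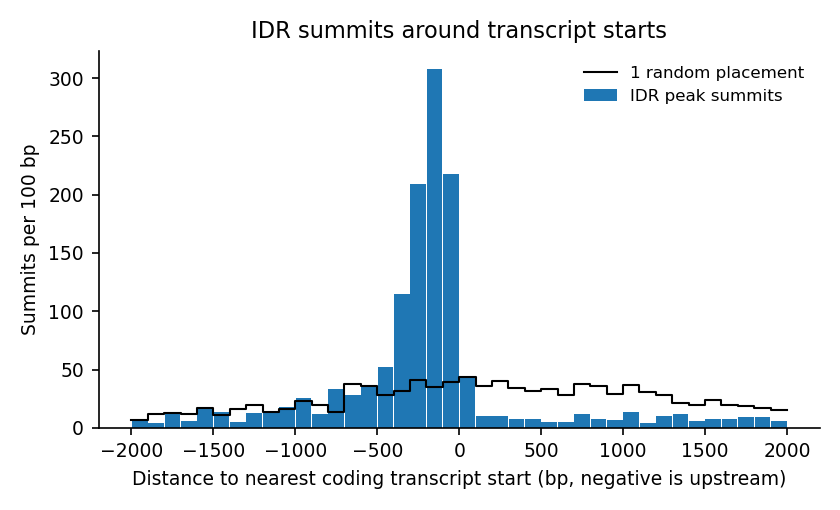
Number of IDR summits (bars) and of summits from 1 random placement (line) per 100 bp of distance to the nearest coding transcript start (x axis, bp, negative is upstream). The tallest bar, 308 summits, lies 200 to 100 bp upstream.

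Chromosomes differed in their share of peaks. Chromosomes III and I held more than their length gives, with 300 peaks on III (1.38-fold, adjusted exact p = 2.768e-08) and 303 on I (1.27-fold, adjusted exact p = 1.607e-05). Chromosomes V and X held fewer, with 238 on V (0.720-fold, adjusted exact p = 1.947e-08) and 211 on X (0.754-fold, adjusted exact p = 6.561e-06). Chromosome II was slightly above its share (274 peaks, 1.14-fold, adjusted exact p = 0.0302), and IV, with 258, did not differ (0.934-fold, adjusted exact p = 0.233; exact binomial tests, two-sided, 6 chromosomes). The call for II was lost under each of the 5 alternatives, where its fold was 1.135 in the higher-signal 50 percent of peaks (adjusted exact p = 0.113), 1.12 without replicate 2 and with close summits counted once, 1.05 without replicate 1 and 1.03 against coding transcript starts. The call for X was lost without replicate 1 (0.940-fold, adjusted exact p = 0.332) and when peaks were compared with coding transcript starts (0.949-fold, adjusted exact p = 0.512).

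The gene lists show which groups of genes were bound. Of 27 lists, 8 were bound more often than other genes and 4 less often. Ribosomal protein genes led, with 60 of 76 bound against 7.43% of other genes (odds ratio 46.7, 95% interval 26.5 to 87.0, exact p = 1.768e-52, adjusted exact p = 4.775e-51). The highest signals were at rpl-20, rps-12, rpl-15 and rpl-23. Translation factors had 19 of 34 bound (odds ratio 15.3, adjusted exact p = 2.591e-12), led by iff-2 (signal 446), eef-1A.1 (445), ifet-1 (417) and eif-3.C (244). The ifet-1 peak also lies in the promoter of rps-1. Oxidative phosphorylation genes were bound in 25 of 47 cases (odds ratio 13.8, adjusted exact p = 3.114e-15), led by cox-10 (signal 830), cox-5A (437), lpd-2 (380) and cox-5B (295). The order of these 2 lists depends on the peaks used, since the odds ratio of translation factors was 8.40 without replicate 1, 13.3 without replicate 2 and 8.78 in the higher-signal 50 percent of peaks, and that of oxidative phosphorylation 10.1, 14.7 and 13.2. The lpd-2 gene was included for its name alone, and its peak is shared with cebp-2.

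Genes of protein folding and turnover and of RNA splicing were also bound more often. Splicing factors had 23 of 52 bound (odds ratio 9.63, adjusted exact p = 4.561e-12), with sftb-6 (signal 481) ahead of snr-4 (210) and of rsp-1 and rsp-2, which share 1 peak (209). The proteasome had 15 of 33 (odds ratio 10.1, adjusted exact p = 1.983e-08), led by the regulatory particle genes rpn-8 (319), rpn-3 (250.3), rpn-12 (248) and rpn-11 (179). Chaperones had 21 of 60 (odds ratio 6.53, adjusted exact p = 7.070e-09), led by the chaperonin genes cct-1 (512), cct-8 (459) and cct-6 (427) and by dnj-22 (371). Cell cycle genes had 17 of 62 (odds ratio 4.56, adjusted exact p = 9.631e-06), with cdc-48.1 first (980), a gene better known for protein extraction and turnover, then plk-1 (184), efl-1 (162) and cdc-6 (152.5). The vacuolar ATPase had 6 of 20 (odds ratio 5.15, adjusted exact p = 0.00939), with vha-12 (124), vha-8 (118.9), vha-9 (95.7) and vha-1 (93.9).

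The 4 lists bound less often were chemoreceptors, nuclear hormone receptors, molting and hedgehog-related genes and ciliated neuron markers. Chemoreceptors had 7 of 1293 bound (odds ratio 0.0609, adjusted exact p = 4.414e-35). Of those 7, sri-5 shares its peak with rsr-1 (signal 196) and srz-97 with clec-57 (68.1), as 39 of the 60 bound ribosomal protein genes and 16 of the 21 bound chaperones share theirs. The highest signal in this list was at srh-16 (215), and the sre-23 peak (70.8) is not shared. Nuclear hormone receptors had 9 of 274 (odds ratio 0.403, adjusted exact p = 0.0108), among them nhr-47 (120), nhr-142 (119.6), nhr-68 (81.6) and nhr-119 (78.5). The nhr-68 region ranked 280 in replicate 2 and 5196 in replicate 1. Molting and hedgehog-related genes had 1 of 103, wrt-3 (odds ratio 0.117, adjusted exact p = 0.0114), whose region ranked 1036 in replicate 2 and 24727 in replicate 1. Ciliated neuron markers had 0 of 60 (odds ratio 0.0986, adjusted exact p = 0.0308).

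The other 15 lists were not past the threshold. They included homeobox genes (2 of 91, adjusted exact p = 0.0974), cuticle collagens (7 of 176, 0.124), tubulins and actins (4 of 21, 0.132), germline markers (11 of 88, 0.177), major sperm proteins (0 of 31, 0.269), aminoacyl-tRNA synthetases (3 of 20, 0.293) and heterochronic genes (2 of 11, 0.293). The insulin and stress pathway had 5 of 105 bound (adjusted exact p = 0.481), intestine markers 1 of 35 (0.665), pharynx markers 8 of 86 (0.665) and epidermis and seam regulators 2 of 23 (0.817). Histones (5 of 72), muscle markers (2 of 34), pan-neuronal markers (2 of 26) and the Wnt pathway (2 of 28) each had an adjusted exact p of 1. Calls appeared for germline markers in the higher-signal 50 percent of peaks (odds ratio 2.70, adjusted exact p = 0.0184), and with promoter windows of 2000 and 500 bp for heterochronic genes (5.26, adjusted exact p = 0.0360) and, on the lower side, homeobox genes (0.206, adjusted exact p = 0.0264). Single members of some of these lists still had peaks of high signal. The highest were at fars-1 (878, rank 32), ric-19 (676, rank 50), nos-3 (588, rank 56), mig-5, on the cct-1 peak (512), and col-8 (452). They were followed by ceh-38 (298), ins-39 (281), his-37 (262), tba-2 (227), pqn-59 (108), sma-2 (103), lin-28 (80.8), erm-1 (56.7) and unc-112 (55.1). The signals at lin-28, erm-1 and unc-112 were below the median of the IDR peaks, 82.2. Of the first 5, fars-1 shares its peak with rbm-5, ric-19 with pmlr-1, nos-3 with Y53C12B.1 and col-8 with rfl-1.

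Against the 8327 genes that had any summit of the pooled list in their promoter, the odds ratios of 9 of the 12 lists were nearer 1, among them 19.6 for ribosomal proteins, 7.06 for translation factors and 0.288 for chemoreceptors, and the vacuolar ATPase call was lost (2.65, adjusted exact p = 0.174). Those of nuclear hormone receptors (0.389), molting and hedgehog-related genes (0.115) and ciliated neuron markers (0.0770) were slightly further from 1. Calls were also lost for nuclear hormone receptors in 3 of 9 alternatives. Their odds ratio was 0.613 without replicate 1 (adjusted exact p = 0.226) and 0.529 with the peaks without the sequence element (adjusted exact p = 0.0983). With the 200 highest-signal peaks no such receptor was bound, the best peak being of rank 478. Ciliated neuron markers lost their call in 7 of 9 and molting and hedgehog-related genes in 4 of 9. Most of the odds ratios of these markers and genes stayed far below 1, from 0.111 to 0.172 in 5 of the 7 for ciliated neuron markers and from 0.145 to 0.154 in 3 of the 4 for molting and hedgehog-related genes. With promoter windows of 2000 and 500 bp that of ciliated neuron markers was 0.483. With the 200 highest-signal peaks the values were 0.562 and 0.328, but no member of either list was bound there, as the wrt-3 peak ranked 1519. Both come from the 0.5 added to each cell and do not show a weaker depletion. No ciliated neuron marker was bound in the main set, so its values from parts of the IDR peaks also follow only how many other genes were bound. With the 200 highest-signal peaks, an alternative chosen after seeing the data, calls were lost for translation factors (6.67) and the proteasome (6.90, adjusted exact p = 0.0574 for both). They were also lost for splicing factors (1.34), cell cycle genes (1.12) and the vacuolar ATPase (adjusted exact p = 1 for these 3). The vacuolar ATPase had no bound member there, its best peak being of rank 459, so its value of 1.66 comes from the 0.5 added. Ribosomal proteins, chaperones, oxidative phosphorylation and chemoreceptors kept their calls in 9 of 9.

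**Figure D3:**
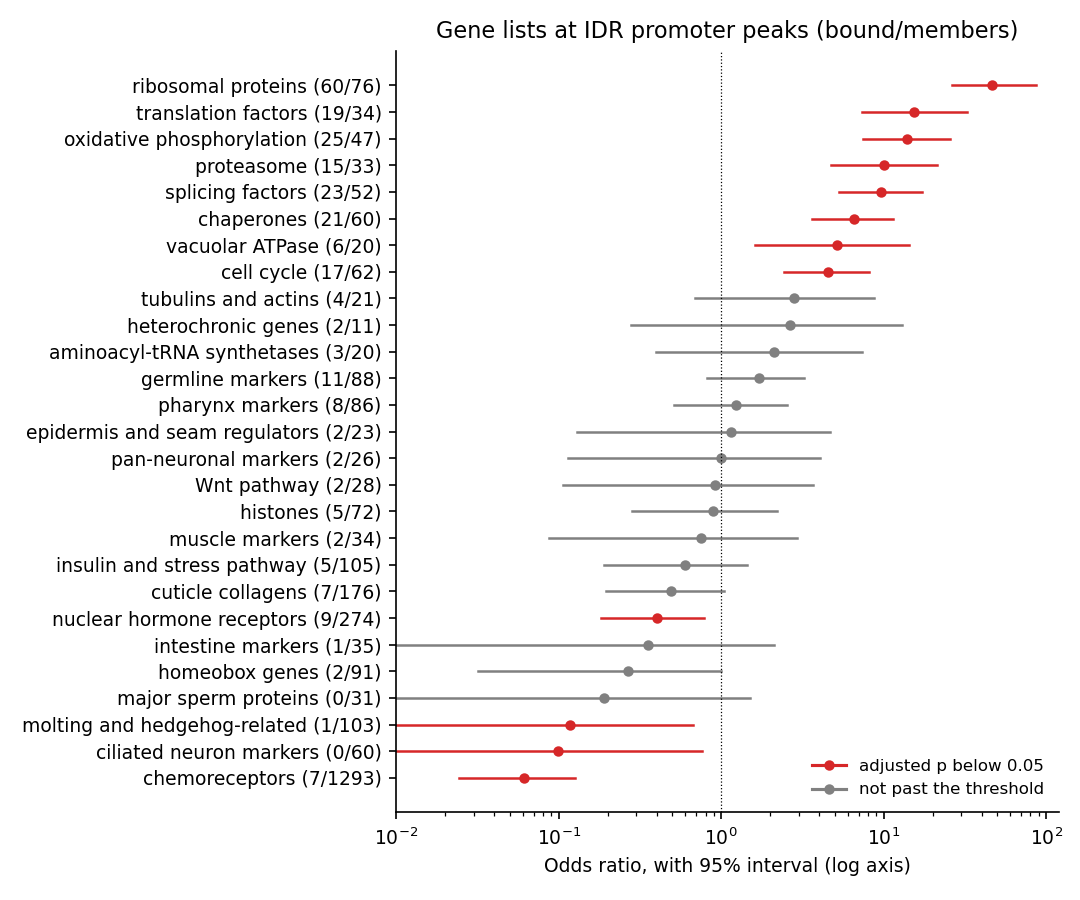
Odds ratio (x axis, log axis) of being promoter-bound for each of the 27 gene lists, with its 95% interval and the number bound over the number of members. Red marks the 12 lists with an adjusted p below 0.05, from ribosomal proteins at 46.7 to chemoreceptors at 0.0609.

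Small noncoding RNA genes were the other group near the peaks. Within 200 bp of snRNA genes lay 23 IDR summits, 23.6-fold more than by random placement. The figure for snoRNA genes was 61 summits (19.97-fold), for tRNA genes 47 (11.9-fold) and for the broad ncRNA class 263 (5.07-fold). Fewer summits than by chance lay near piRNA genes (18, 0.368-fold) and pseudogenes (12, 0.201-fold; adjusted permutation p = 0.00333 for each of the 6 classes, two-sided permutation test over 10 classes, with the smallest raw p possible). Those near lincRNA (7 summits, adjusted permutation p = 0.522), antisense RNA (4, 0.435), miRNA (4, 0.365) and rRNA genes (0, 1) did not differ beyond the threshold. The share outside the promoter windows of coding genes was 70.2% for summits near tRNA genes, 52.5% for snoRNA, 39.5% for ncRNA and 34.8% for snRNA genes, and these counts were not separated from the promoter preference. The highest of the 47 tRNA-associated summits ranked 351. With a distance of 500 bp the folds fell to 11.96 for snRNA, 11.4 for snoRNA, 5.94 for tRNA and 3.01 for ncRNA genes, while miRNA genes (3.34-fold) and antisense RNA genes (2.91-fold) also passed (adjusted permutation p = 0.0050 for both). Without replicate 2, miRNA genes passed as well (3.31-fold, adjusted permutation p = 0.0457), and in the higher-signal 50 percent of peaks the fold for tRNA genes was 5.26 and for snRNA genes 35.9.

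Sequence under the summits was compared with that of the flanks of the same peaks. The 8-mer CTGCGTCT, known from promoters of ubiquitously expressed worm genes, was found in 16.2% of the 200 bp windows and 0.821% of the flanks (odds ratio 23.3, adjusted exact p = 2.634e-95). GA repeats were found in 12.4% and 1.39% (odds ratio 10.03). The internal promoter elements of tRNA genes were rare but also higher, the B box in 1.52% of windows (odds ratio 12.2) and the A box in 0.694% (11.1). The SP and KLF GC box (3.50), the KLF CACCC motif (3.48), the E2F motif (3.04), the CACGTG E-box (1.65) and the forkhead motif (1.59) completed the 9 motifs that were higher.

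Lower at summits were the 3' splice site (10.4% against 23.1%, odds ratio 0.384), the homeobox motif (0.444), the heat shock element (0.542), the TATA box (0.590), the GATA motif (0.603), the GATA core (0.716) and NF-Y (0.813). The other 7 of the 23 motifs were not past the threshold. Among all 2080 six-mers, 599 were higher and 656 lower at summits. Base composition was not matched between summits and flanks. Calls for single motifs and six-mers, higher or lower, were therefore not separated from a general difference in composition. The 5 of highest odds ratio were GCGCGC (11.2), CGCGCG (10.6), ACGCAG (8.94), ACGCGC (8.27) and GACGCA (7.91), and ACGCAG was present in 26.2% of windows against 3.82% of flanks. Against promoter summits outside the IDR peaks the odds ratios fell, to 3.601 for CTGCGTCT, 3.54 for GA repeats and between 3.49 (ACGCAG) and 5.004 (GCGCGC) for the 5 six-mers, and the forkhead and KLF CACCC calls were lost (adjusted exact p = 0.471 and 0.119). Calls were also lost for the E-box without replicate 2 (1.27, adjusted exact p = 0.157), for the A box in the higher-signal 50 percent of peaks (6.01, adjusted exact p = 0.404), and without replicate 1 for the forkhead motif (1.44, adjusted exact p = 0.0519) and the GATA core (0.982, adjusted exact p = 0.928). Calls appeared on the lower side for T blocks in 3 of 5 alternatives (0.273 in windows of 100 bp), for AP-1 in windows of 100 bp (0.409) and, against promoter summits outside the IDR peaks, for the nuclear receptor motif (0.711), and on the higher side there for the CAGCTG E-box (1.37). The GATA motif turned direction without replicate 1 (odds ratio 1.11, adjusted exact p = 0.240).

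**Figure D4:**
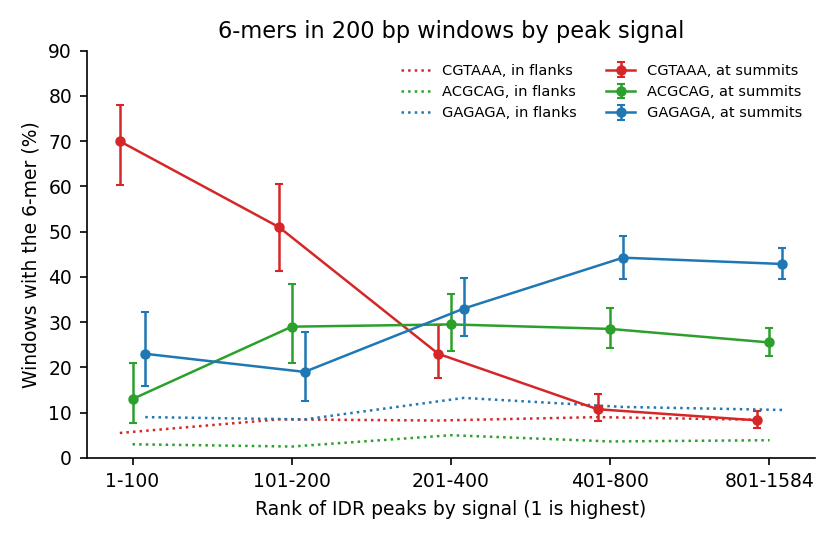
Percent of 200 bp windows that hold each six-mer (y axis) by rank class of the IDR peaks (x axis, rank 1 is the highest signal), with Wilson 95% intervals for summits and dotted lines for flanks. The six-mer CGTAAA, chosen after its values were seen, falls from 70% in ranks 1 to 100 to 8.29% in ranks 801 to 1584, whereas ACGCAG is lowest, at 13%, in ranks 1 to 100.

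The transgene could add reads at the endogenous coordinates of R02D3.7, so its surroundings were described separately. Within 20 kb of rcat-1 (IV, 253619 to 255429, minus strand) lay 1 IDR peak, the promoter peak of rank 1. The pooled list held 6 regions there and the replicate 2 list 3, against genome averages of 12.5 and 12.2, whereas the replicate 1 list held 19 against 12.5. The unc-119 gene (III, 10902641 to 10908935) had 0 IDR peaks within 20 kb and 18 pooled regions, the highest of rank 2486. These counts are given without a test, and a peak at the tagged gene cannot be separated from extra transgene copies with these lists.

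**Figure D5:**
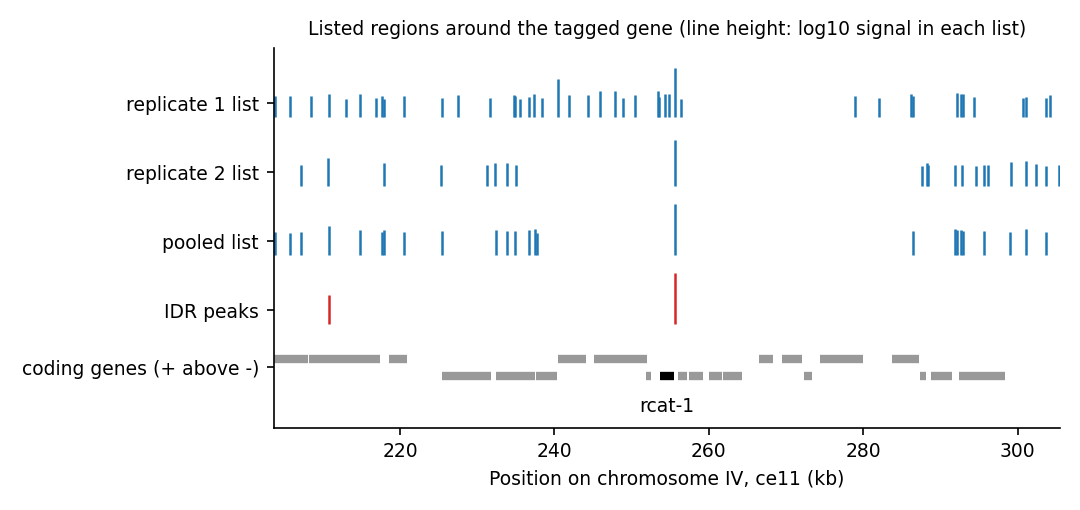
Regions of each list around rcat-1 on chromosome IV (x axis, kb, ce11), drawn as lines whose height is the log10 signal within each list. The tallest line, with its summit at 255641, stands between stretches without regions in the pooled and replicate 2 lists.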

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

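All tests in this part were chosen after the results they concern had been seen, and 2 of them replaced an earlier form, which is also given.

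The density of relaxed regions along the chromosomes was not compared in the report, and those of replicate 2 were crowded on parts of chromosome I. Of its 30 windows of 500 kb, 14 held over 1.5 times the median of all 201 windows (15 such windows in all), with a median of 2.201 times, in I, 1 to 5000000, 6500001 to 8000000 and 9000001 to 9500000. A feature of the reference or of the shared control would raise replicate 1 in the same windows, where its highest value was 1.45 times its own median, below the 1.5 set for this test. That bound replaced an earlier one, a replicate 1 median below 1.2, and the median was 1.16 with a 95% bootstrap interval of 1.11 to 1.27, which leaves a weaker shared feature open. A gain of DNA copies in replicate 2 is open too. IDR peaks in these windows ranked a median of 17 places higher by replicate 2 than elsewhere (95% interval -29 to 52). No biological explanation was tested, as there is 1 group. Chromosome I was not the only place where the replicates differed. In IV, 16500001 to 17000000, replicate 2 held 0.0791 times its median and replicate 1 0.477 times. In IV, 17000001 to 17493829, the values were 0.109 and 0.791 times. This sparse stretch was not tested.

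Near the tagged gene, the replicate 1 list held a region that is in neither the pooled nor the replicate 2 list (IV, 240360 to 240669, summit 240520, in a UTR of cogc-8), with a signal of 279.5 and rank 85 of 30000. It is 1 of 14 such regions within 20 kb of rcat-1, and it lies in a stretch of 17.5 kb left of the rcat-1 peak (IV, 237901 to 255405) without pooled regions, followed on the right by one of 30.3 kb (IV, 255893 to 286222). Chance is open for the shorter gap taken singly, because 2.76% of all gaps in the pooled list were as long, the first test made, whereas 0.830% were as long as the longer one, below the 1% bound of that test. A later test asked for gaps that long on both sides of 1 region, and 0.193% of pooled regions (58 of 29988) had them, which argues against chance for the pair only as far as a measure picked after the first result can. Sequence that no library can list is argued against on the left, where replicate 1 held 12 regions (average 5.24), and cannot be decided on the right, where it held 3 (average 9.07), while extra transgene copies in the worms or in the control DNA remain open and no biological explanation was tested.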

How the results depend on the processing

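The alternatives on the 200 highest peaks, the peaks without the sequence element, chromosome I and the tagged locus in each replicate were chosen after seeing the data. Of 45 values of main results under an alternative, 38 stayed on their side of the threshold or within 1.5 times, and of 482 single tests 406 did. Spearman's rho between replicates ranged from 0.624 to 0.785 and the promoter share from 60.2% to 79.4%. Using the higher-signal 50 percent of peaks left 792 peaks and 242 kb by construction. The number of chromosomes that differed from their share, 5 at first, was 3 to 4 with 1 replicate left out and 3 against coding transcript starts, and the cause was not tested. Of the 12 gene lists past the threshold, 4 remained with the 200 highest-signal peaks, ribosomal proteins, chaperones, oxidative phosphorylation and chemoreceptors. The odds ratio fell from 15.3 to 6.67 for translation factors, 10.1 to 6.90 for the proteasome, 9.63 to 1.34 for splicing factors and 4.56 to 1.12 for cell cycle genes, and the cause was not tested. The vacuolar ATPase, at 5.15 before, had no member bound by these 200 peaks. Its value of 1.66 comes from the 0.5 added to each cell and is not an enrichment. Without chromosome I, 10 lists passed and the promoter share was 67.5%. With the peaks that lack the element, 9 lists passed. The number of peaks near rcat-1 was 2 within 50 kb, by construction, and 1 to 2 with 1 replicate left out. The odds ratio of the GATA motif was 0.481 without replicate 2, between 0.380 and 0.574 over all alternatives but 1, and turned to 1.11 without replicate 1 (adjusted exact p = 0.240), and the cause was not tested. The 55 genes named from the lists were chosen because they were bound, and of them 47 were bound in the higher-signal 50 percent of peaks, 45 with promoter windows of 500 and 100 bp, 55 with 2000 and 500 bp, 54 without replicate 1 and 52 without replicate 2. No paired analysis was possible because there is 1 group. Read depth is unknown, so regions near the end of each relaxed list cannot be told from background.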

Other observations

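The tests of the sequence element below were set down before their results were seen, except those of the seed on separate chromosomes and of the columns beside it, whereas the element itself, its seed six-mer, the rank classes and the genes named in this part were chosen after the values were seen.

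Peaks near noncoding genes included those of trans-splicing. The SL2 RNA genes sls-2.4 and sls-2.1, whose products supply the leader spliced onto downstream genes of operons, had IDR summits at a distance of 25 bp (I, 4171973 to 4172559, signal 575, rank 57) and 33 bp (II, 5844647 to 5845122, signal 521, rank 65). They were the highest among the 23 peaks near snRNA genes, whose median rank was 379. The snoRNA-associated peaks were weaker, with a median rank of 953 and the highest at rank 259, near F39B2.14 and the promoter of rps-26 (I, 14759417 to 14759645). The tRNA-associated peaks had a median rank of 1113. Copies of these small genes are often near-identical, so single assignments are uncertain.

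Sequence content changed with peak signal. The six-mer CGTAAA, outside the 5 named by rule, was found in 70% of windows in ranks 1 to 100, 51% in ranks 101 to 200, 23% in ranks 201 to 400 and 8.29% in ranks 801 to 1584, where the flanks had 8.42%. The six-mer GAGAGA went the other way, from 23% (Wilson 95% interval 15.8 to 32.2) in ranks 1 to 100 to 42.9% (39.4 to 46.3) in ranks 801 to 1584. ACGCAG rose from 13% (7.76 to 20.98) in ranks 1 to 100 to 29% (21.01 to 38.5) in ranks 101 to 200 and stood at 25.5% in ranks 801 to 1584. A matrix was built from 74 occurrences in those of the first 200 peaks that lie on chromosomes I to III, with the consensus CGTAAATCnACAC, and was tested on IV, V and X, although the seed and the rank classes had been seen on all chromosomes.

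The hypothesis tested was that peaks of high signal share a longer element around CGTAAA, which may be a binding site. The matrix was found in 55.2% of the 96 held-out peaks (Wilson 95% interval 45.3 to 64.8) against 4.17% of their flanks. Of held-out peaks of ranks 801 to 1584, 6.74% had it. CGTAAA alone was in 56.25% of the windows of the same 96 peaks and 9.375% of their flanks. The share at the peaks therefore does not by itself show a longer element, for which only the test of the columns beside the seed, given below, speaks. Shuffling all columns, after which 0 of 100 matrices separated peaks from flanks as far, partly repeats the first sight of the seed, but base composition is argued against by 2 later tests. CGTAAA, which had the largest difference of all six-mers on I to III alone, differed by 46.9 percentage points on IV, V and X, a difference that 0% of the other six-mers of its letters reached (at most 19.3), and 0 of 100 shuffles of the columns beside it scored its 59 held-out occurrences as high. For an element of promoters in general, other promoter summits were searched, and 4.91% of 4091 held it (4.29 to 5.62). These summits all lie below the IDR peaks in pooled signal, and the element was picked for falling with signal. Their share shows only that promoters of lower signal rarely held it, and cannot decide on promoters of high signal in general. Copies of 1 repeated sequence are argued against by the 4.13% of 121 windows that share a 20-mer. Whether rcat-1 binds the element itself or is brought there by another protein, and what sets the peaks without it, remain open and untested. It is also open whether these peaks depend on rcat-1, since no library of an untagged strain or of another tagged protein was analysed here.

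On the held-out chromosomes the element was present at 9 of the 10 peaks among the first 20, the rcat-1 promoter included and the dld-1 peak excepted, and lay a median of 23 bp from the summit in the first 200 peaks. The other 10 of the first 20, on the chromosomes used to build the matrix, all had it. Held-out peaks at ribosomal protein promoters had it in 55% of 20 cases (Wilson 95% interval 34.2 to 74.2), other held-out promoter peaks in 18.8% of 437 (15.4 to 22.7) and held-out peaks outside promoters in 6.8% of 250 (4.29 to 10.6). On I to III, 29.7% of 37 peaks at ribosomal protein promoters had it (17.5 to 45.8). Other promoter peaks there had it in 19.8% of 610 cases (16.9 to 23.2), so these intervals overlapped. The groups were not matched for signal, with which the element became more frequent. These shares therefore do not tie it to ribosomal protein genes apart from signal. On all chromosomes, those used to build the matrix included, through the 262 peaks with the element, 22 of 76 ribosomal protein genes, 9 of 47 oxidative phosphorylation genes and 1 of 62 cell cycle genes were bound. Through the 1322 peaks without it, these numbers were 38, 16 and 16. The counts also follow the number of peaks in each group. Against other genes, the odds ratios of the 3 lists were 23.9, 13.4 and 0.906 with the element and 16.2, 8.19 and 5.52 without it. The cell cycle value with the element rests on 1 gene, 1.61% of the list against 1.78% of other genes. The difference between the lists was not tested.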
